A study of Rattus norvegicus with 20 samples.

How the data were processed

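Total RNA was extracted from tissue labelled brain cortex of 20 male Sprague Dawley rats, 20 weeks old and weighing 250 to 300 g, and hybridised as biotin-labelled cRNA to Affymetrix arrays, per the labels' protocols. Groups (10 rats breathing oxygen, 10 breathing isoflurane) and replicate numbers came from the sample titles. The deposited values were linear array intensities (MAS5 signal), made with MAS5 and Affymetrix Expression Console per the submitters' processing notes. Versions and settings were not given in the sources used here. The values themselves showed that each array had been scaled, since the mean after trimming 2% from each end lay between 500.1 and 500.2 on every array. Detection calls were not used here, so signal near background could not be told from absence of a transcript, and MAS5 scaling makes changes relative to the average transcript of an array.

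The table held 31099 probe sets, of which 57 were controls. Values under 1 (2015 of them) were raised to 1 and log2 was taken, with no further normalization. Of 31042 probe sets that are not controls, 18625 had a mean log2 signal above the 40th percentile (6.62) and were tested. A platform annotation named 1 gene symbol for 20826 probe sets, several for 436 and none for 9780, and only those with 1 symbol were named. Symbols were brought up to date by gene ID through an annotation table of the rat assembly GRCr8, which was used for names alone, and no coordinates are given since the array values name no genome build. A gene was represented by its brightest tested probe set, which gave 10315 genes.

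Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05, isoflurane minus oxygen, no covariate). Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and fry beside it. Of 986 listed symbols 2 matched no gene of the tables. Networks joined gene pairs with an absolute Pearson r of at least 0.8 within a group, over the 2000 brightest genes, and were compared with 100 splits of values centred per group, as was the ratio of SDs. The 3'/5' ratio of control transcripts was compared with a permutation test of 100000 resamples. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for networks, permutations and plots.

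The tests, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. The rule took, among genes past the threshold, up to 12 with the largest rise and 12 with the largest fall, for each list the 3 members with the lowest p where the list or a member passed and otherwise the 1 lowest, 14 genes named in advance (1 of them is not reported here), and the 5 genes with most edges in each network, skipping genes without a proper symbol. Alternatives were quantile normalization, arrays centred on their medians, pseudocounts of 16 and 64, eBayes without the trend or made robust, array weights, the replicate number as a block, the 3'/5' ratio as a covariate, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, other network settings, and each array left out in turn. Chosen after seeing the data were the 2 sets of arrays, which were parted at the largest gap in the mean log2 signal of Gabra6, Pcp2, Cbln1, En2 and Fat2, fits with the set as a block or within a set, and fits without the 4 isoflurane arrays that stood apart.

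The limma fits were tested on simulated values with the real means and residual spread and 200 of 18625 probe sets changed. With 2 groups of 10 arrays, 32% of changes of 0.5, 68% of 1, 96% of 2 and 100% of 3 on the log2 scale were recovered, with 9 false calls among 157. With the array set as a block the shares were 52%, 92%, 100% and 100%, with 8 false calls among 180. The simulated noise was drawn independently for each probe set. These shares and false calls therefore do not cover variation that many probe sets share, such as arrays that stand apart.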

Results

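Gene expression was measured on 1-colour Affymetrix rat arrays in brain cortex, as labelled, from 20 male Sprague Dawley rats. Of these, 10 breathed oxygen alone and 10 breathed oxygen with 2% isoflurane, a volatile anaesthetic, for 15 minutes, and tissue was taken 6 hours later. The dose was 1.4 MAC, the unit of anaesthetic potency. One array was made per rat, so p-values measure the spread between animals. Over all 20 arrays without a block, that spread includes the difference between the 2 sets of arrays described below. The submitters' design text states that the profiles were made to build gene networks. The deposited signals had a trimmed mean between 500.1 and 500.2 on each array, and array medians ran from 7.20 to 7.57 on the log2 scale. The number of arrays limits the precision. No pair of arrays held the same values, the highest correlation between any pair being 0.982.

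Within both groups the arrays fell into 2 sets by genes of different brain regions, chosen after their values were seen. On 11 arrays the signal of Pcp2, a gene of cerebellar Purkinje cells, lay between 13.60 and 14.17 on the log2 scale. On the other 9 it lay between 4.46 and 10.67. Gabra6, a GABA-A receptor subunit of cerebellar granule cells, ran from 13.40 to 14.10 on the 11 arrays and from 2.97 to 10.70 on the 9. Fezf2, a transcription factor of deep-layer cortical neurons, went the other way, with 1.31 to 6.96 on the 11 arrays and 8.69 to 9.43 on the 9. Emx1, a transcription factor of the dorsal forebrain, ran from 3.40 to 7.28 and from 8.37 to 8.93. The 11 arrays were oxygen replicates 5 to 10 and isoflurane replicates 1, 3, 7, 8 and 9. The 9 arrays were oxygen replicates 1 to 4 and isoflurane replicates 2, 4, 5, 6 and 10, and Fisher's exact test found no tie between set and group (p = 1). The first principal component held 58.0% of the variance and separated the 2 sets. The counts of probe sets, the lists that passed and the 3'/5' ratio are therefore also given with the array set as a block and within each set, and networks and spread with values centred within group and set.

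**Figure D1:**
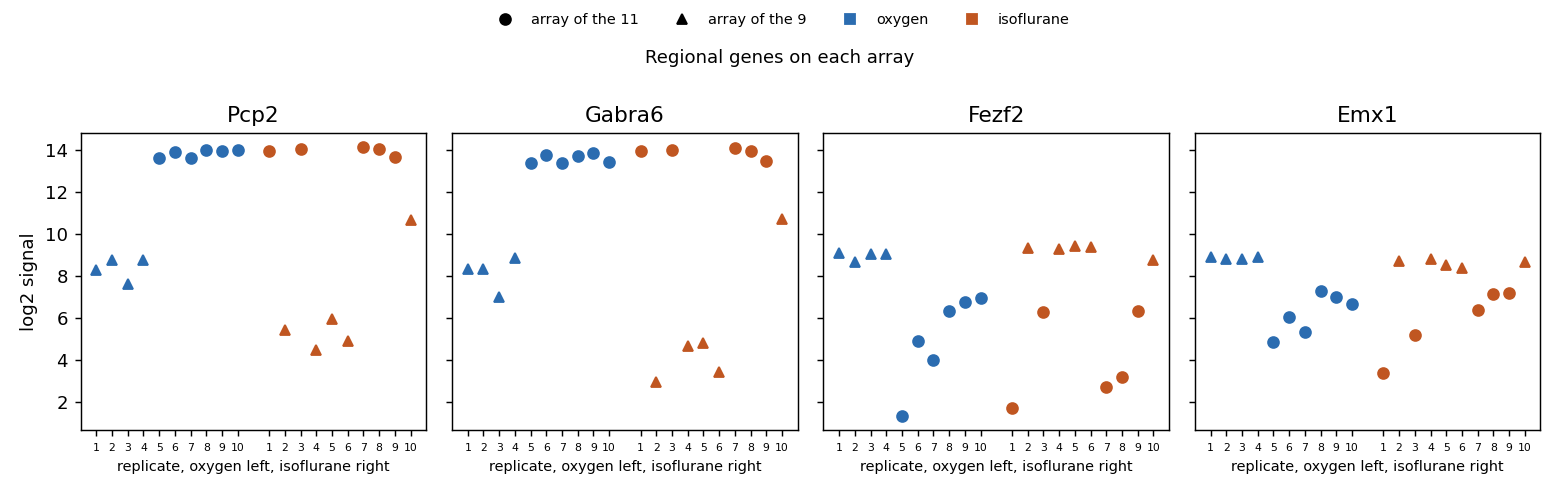
Each point is 1 array, placed by group and replicate number, and the vertical axis is the log2 signal of the gene named above the panel. Circles are the 11 arrays with Pcp2 between 13.60 and 14.17, triangles the 9 arrays with Pcp2 between 4.46 and 10.67, and both kinds occur in both groups.

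The first comparison asked which transcripts differed 6 hours after isoflurane. Over all 20 arrays falls outnumbered rises, which was not so within the 9 arrays alone: 59 of the 74 probe sets past the threshold were lower after isoflurane and 15 were higher, of 18625 tested. The lowest adjusted p belonged to Nr1d1, a transcriptional repressor of the circadian clock (also called Rev-erb alpha). Its log2 signal was 9.96 ± 0.24 (SD, n = 10) after oxygen and 9.02 ± 0.34 after isoflurane, a fall of 0.94 in log2 terms in limma (change -0.94 ± 0.13 SE, adjusted p = 0.00907) with 10 of 10 isoflurane arrays below the oxygen mean. Vegfb, a growth factor of the vascular endothelial growth factor family, fell by 0.76 ± 0.12 SE (adjusted p = 0.0169, 10 of 10 arrays). Fa2h, the enzyme that makes hydroxylated fatty acids for myelin lipids, changed by -0.60 ± 0.10 SE (adjusted p = 0.0276, 10 of 10 arrays).

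The largest falls were in Epn1, an adaptor of clathrin-mediated endocytosis, at -1.65 ± 0.34 SE, and in the RNA-binding protein gene Raver1, at -1.37 ± 0.29 SE, each with 9 of 10 isoflurane arrays below the oxygen mean. Prr12 (-1.03) and Ptpn23, a phosphatase of endosomal sorting (-0.97), followed. Mknk2, a kinase of the translation factor eIF4E (-0.87), Sec31a, a coat protein of vesicles leaving the endoplasmic reticulum (-0.84), and Sbf1 (-0.81) also fell. So did Kcnc4, a fast voltage-gated potassium channel (-0.80), the kinase gene Cdc42bpb (-0.72) and Nalf2, an auxiliary factor of the sodium leak channel (-0.72). Their adjusted p-values ran from 0.0295 for Cdc42bpb to 0.0485 for Kcnc4. Among rises, only 8 named genes had a brightest probe set that passed. Frg1 rose by 1.00 ± 0.19 SE (adjusted p = 0.0448) and the linker histone gene H1f4 by 0.72 ± 0.16 SE (adjusted p = 0.0485). Grpel2, a cochaperone of the mitochondrial matrix, rose by 0.64 ± 0.12 SE (adjusted p = 0.0317), and Cert1, which carries ceramide between membranes, by 0.51 ± 0.11 SE (adjusted p = 0.0485). The splicing factor gene Sf3b5 rose by 0.44, the polycomb gene Pcgf5 by 0.43, Cfap36 by 0.37 and the kinase gene Ttbk2 by 0.31, a gene whose 2 tested probe sets differed in sign. All 10 isoflurane arrays lay above the oxygen mean for these 8 genes, except for Sf3b5 with 9 of 10.

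**Figure D2:**
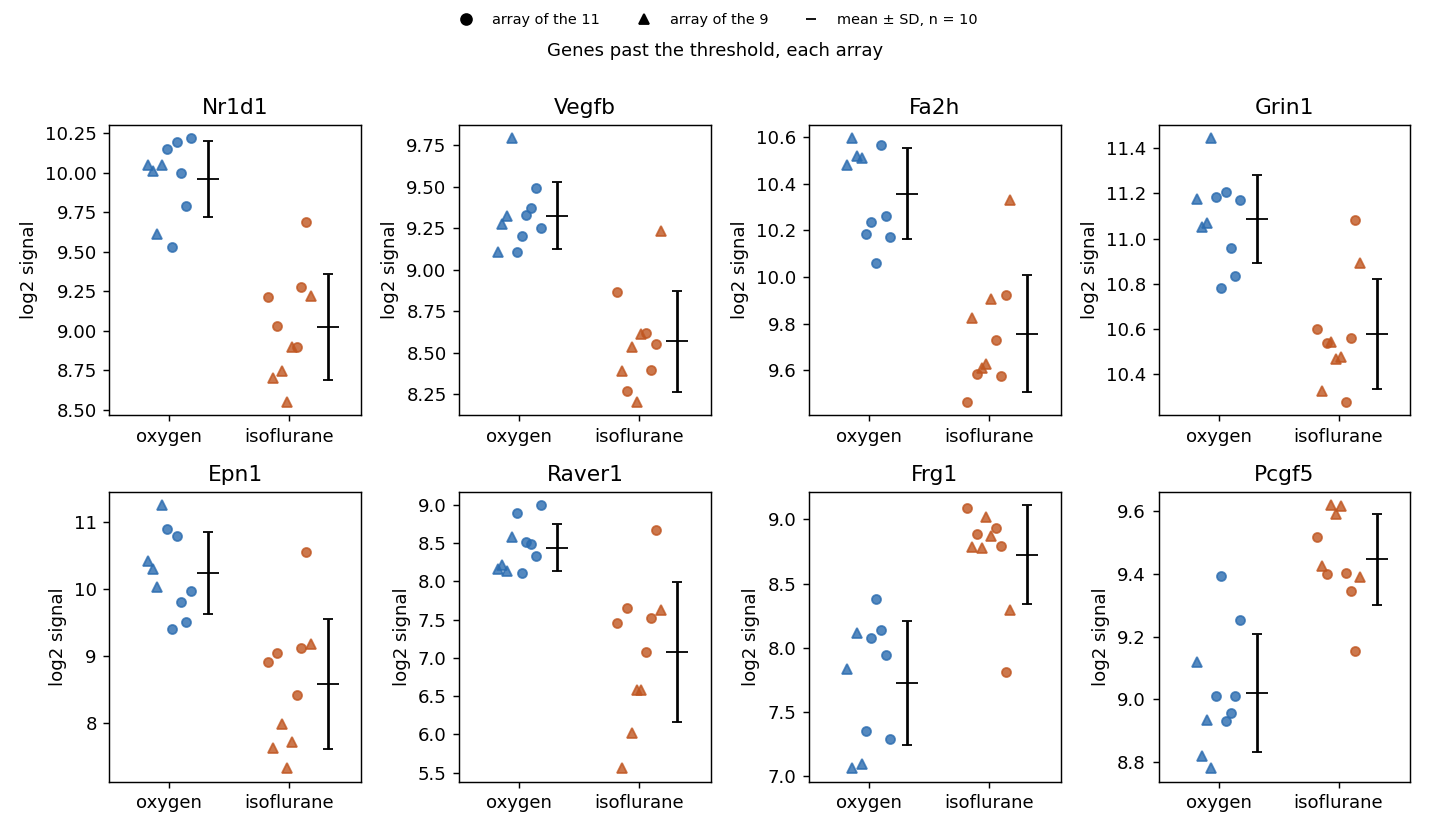
Each point is the log2 signal of 1 array, circles for the 11 arrays and triangles for the 9, and black bars give the mean ± SD of 10 arrays per group. Nr1d1 averaged 9.96 after oxygen and 9.02 after isoflurane, and Frg1 averaged 7.73 and 8.73.

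With the array set as a block, 1372 probe sets passed, 892 lower and 480 higher, and all 74 stayed among them. Nr1d1 then changed by -0.92 ± 0.12 SE (adjusted p = 0.00204). Its value was -0.76 within the 11 arrays (adjusted p = 0.306) and -1.11 within the 9 (adjusted p = 0.00602). Within the 11 arrays the value of Epn1 was -0.85 (adjusted p = 0.37) and within the 9 it was -2.53 (adjusted p = 0.00602), and those of Frg1 were 0.84 and 1.22 (adjusted p = 0.331 and 0.0107). All 74 probe sets, which the fit over both sets had selected, had the same sign in both. Within the 11 arrays alone limma called 0 probe sets, with 2376 at an unadjusted p under 0.05, and within the 9 alone it called 3469, 1382 lower and 2087 higher, of which 2145 had the same sign within the 11. The difference between groups itself varied between the sets for 1897 probe sets (limma, interaction term). Isoflurane replicates 2, 4, 5 and 6 stood apart from the other 5 of the 9 arrays, and with these 4 left out limma called 0 probe sets, with 2488 at an unadjusted p under 0.05. The median log2 change of the 74, turned to the direction found over all arrays, was then 0.47 (median SE 0.13), against 0.60 (median SE 0.12) over all arrays. Leaving out single arrays moved the count by over 1.5 times in 18 of 20 cases, 16 of them downwards, from 2 without isoflurane replicate 2 to 838 without isoflurane replicate 9, and only Nr1d1 and Nectin1, a cell adhesion gene, passed in all 20 fits that left 1 array out.

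The second comparison asked whether gene lists fixed beforehand shifted together. Of 30 lists, 3 passed in camera, all upwards: cytosolic ribosomal proteins (adjusted p = 2.41e-06), oxidative phosphorylation genes (adjusted p = 3.65e-06) and proteasome subunits (adjusted p = 0.00678). None of the 3 held when camera estimated the correlation between genes (adjusted p = 0.92 with an estimated correlation for each). The shifts were small, with a median log2 change of 0.14 over 40 ribosomal genes, 0.09 over 69 oxidative phosphorylation genes and 0.08 over 39 proteasome genes. They depended on the scaling, with medians of 0.06, 0.06 and 0.09 after quantile normalization and of 0.07, 0.03 and 0.01 with arrays centred on their medians. No single member of these lists passed over all genes tested. Adjusted over the list alone, 1 ribosomal gene rose, Rpl4 (0.27 ± 0.07 SE), 1 oxidative phosphorylation gene rose, the complex I gene Ndufb8 (0.42 ± 0.10 SE), and no proteasome gene did. The next members by p were Rps9 (0.26, adjusted p = 0.186), Rpl37a (0.30, adjusted p = 0.252), Ndufs4 (0.28, adjusted p = 0.144) and Ndufa11 (0.21, adjusted p = 0.144). Among proteasome genes they were Psmd8 (0.16, adjusted p = 0.206), Psmb2 (0.22, adjusted p = 0.209) and Psmb1 (0.18, adjusted p = 0.209).

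The same 3 lists passed with the array set as a block, with adjusted p = 4.67e-05 for ribosomal and for oxidative phosphorylation genes and 0.0106 for proteasome subunits, and none with an estimated correlation (adjusted p = 0.88 each). Their medians were 0.24, 0.15 and 0.16 within the 11 arrays (adjusted p = 3.63e-10, 3.56e-12 and 1.5e-08) and 0.01, 0.01 and -0.06 within the 9 (adjusted p = 0.662, 0.737 and 0.931). At the preset correlation 6 lists passed within the 11 arrays, all upwards. Besides these 3 they were heat shock proteins (median 0.12, adjusted p = 0.0018), oxidative stress response genes (0.13, adjusted p = 0.00256) and endoplasmic reticulum stress genes (0.13, adjusted p = 0.0273). Within the 9 arrays the medians of these last 3 were -0.21, -0.11 and -0.10 (adjusted p = 0.313, 0.403 and 0.662). Within the 9 arrays none passed by camera (4 at an unadjusted p under 0.05). With the 4 isoflurane arrays left out 10 lists passed, the ribosomal, oxidative phosphorylation and proteasome lists and heat shock proteins upwards. Glutamate receptor genes, synaptic vesicle genes, excitatory neuron markers, activity-regulated genes, myelin markers and endothelial markers passed downwards. With the block added to that fit 7 lists passed, and of the 6 only glutamate receptor genes and endothelial markers did. All these calls used the preset correlation. With an estimated correlation camera passed 0 lists within the 11 arrays (3 at an unadjusted p under 0.05, lowest adjusted p 0.341), within the 9 (0 at an unadjusted p under 0.05) and with the 4 arrays left out, without or with the block (0 each, lowest adjusted p 0.468 and 0.466). The difference between the sets was not tested for lists. With arrays centred on their medians the proteasome list no longer passed (adjusted p = 0.128).

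No list of synaptic genes passed over all 20 arrays, and only 1 member of these lists did. With the 4 isoflurane arrays left out, glutamate receptor genes (median -0.29, adjusted p = 0.0291) and synaptic vesicle genes (median -0.09, adjusted p = 0.0449) passed downwards, and the former also with the block added (-0.15, adjusted p = 0.0245), in each case at the preset correlation only. Excitatory neuron markers had a median of -0.64 in that fit (adjusted p = 0.0096 at the preset correlation, 0.588 at an estimated one). With the block added their median was -0.24 (adjusted p = 0.0509 at the preset correlation). That fit was unbalanced between the sets, since 5 of its 6 isoflurane arrays and 6 of its 10 oxygen arrays were among the 11. Of 29 glutamate receptor and scaffold genes, 1 fell over all genes tested, and 3 fell adjusted over the list alone (camera adjusted p = 0.394). The member that passed was Grin1, the obligatory subunit of NMDA receptors, at -0.51 ± 0.10 SE (adjusted p = 0.0451). Its other tested probe set had the opposite sign. The postsynaptic scaffold genes Shank3 (-0.88, adjusted p = 0.0748) and Shank2 (-0.51, adjusted p = 0.0953) did not pass over all genes. In the blocked fit 8 members fell and 1 rose, and the list median was -0.14 within the 11 arrays and -0.28 within the 9. Of 40 synaptic vesicle and release genes none passed over all genes and 3 fell adjusted over the list alone (camera adjusted p = 0.374). Slc17a7, a vesicular glutamate transporter gene, had the lowest p in that list and among 24 excitatory neuron markers (-0.67 ± 0.19 SE, adjusted p = 0.103). It was bright on both sets, from 10.84 to 12.52 on the 11 arrays and from 11.31 to 13.06 on the 9. In the blocked fit 7 of the 40 fell.

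Among 30 potassium and HCN channel genes 1 fell, Kcnc4 (-0.80 ± 0.17 SE, adjusted p = 0.0485), and the same 1 fell adjusted over the list alone (camera adjusted p = 0.792). The pacemaker channel gene Hcn2 changed by -0.59 (adjusted p = 0.116) and Kcnj6 by -0.30 (adjusted p = 0.268). Among 21 circadian clock genes Nr1d1 alone passed over all genes, and 2 fell adjusted over the list alone, Nr1d1 and the clock-controlled deubiquitinase gene Usp2 (-0.37 ± 0.10 SE, adjusted p = 0.0852). Cry2, a core repressor of the clock, changed by -0.15 (adjusted p = 0.328), and camera gave no shift of that list (adjusted p = 0.851). Among 23 oligodendrocyte and myelin markers Fa2h alone fell, over all genes and adjusted over the list alone (camera adjusted p = 0.792). Sox10, the transcription factor of the oligodendrocyte lineage, changed by -0.62 (adjusted p = 0.188) and Enpp6 by -0.35 (adjusted p = 0.232). In the blocked fit 4 channel genes fell and 1 rose, 2 clock genes fell and 3 myelin genes fell.

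In the other 23 lists no member of 487 list places passed over all genes tested. Adjusted over the list alone, 1 rose and 12 fell, and camera's adjusted p-values ran from 0.374 to 0.854. The block changed calls of members: in the blocked fit 3 rose and 30 fell over all genes tested. Of the members that led these lists by p, Fbxo33 rose there and Hyou1, Me1, Pfkl, Rela, Gsk3a, Gabbr1, Cacnb3, Slc17a7 and Atp1b2 fell, with adjusted p from 0.00796 for Cacnb3 to 0.0394 for Rela. By lowest p, the stress and signalling lists were led by Fbxo33 (0.27, adjusted p = 0.0751) among activity-regulated genes and Ehd3 (-0.48, adjusted p = 0.219) among glucocorticoid-responsive genes. The small heat shock gene Cryab (0.30, adjusted p = 0.193), the endoplasmic reticulum chaperone gene Hyou1 (-0.82, adjusted p = 0.0696) and the malic enzyme gene Me1 (-0.34, adjusted p = 0.12) led heat shock, endoplasmic reticulum stress and oxidative stress. The glycolytic gene Pfkl (-0.85, adjusted p = 0.0748), the NF-kappaB subunit gene Rela (-0.29, adjusted p = 0.113), Bcl2l1 (-0.37, adjusted p = 0.154) and Gsk3a (-0.81, adjusted p = 0.0771) led hypoxia, inflammation, apoptosis and amyloid and tau genes. Gabbr1, a GABA-B receptor subunit, led the inhibitory receptor list (-0.39, adjusted p = 0.0522), and Cacnb3 the sodium and calcium channel list (-0.87, adjusted p = 0.0621). The leading cell type and region markers were Gad2 (0.52, adjusted p = 0.207) for interneurons, Atp1b2 (-0.44, adjusted p = 0.132) for astrocytes and Lhfpl3 (-0.20, adjusted p = 0.352) for oligodendrocyte precursors. They were C1qb (0.37, adjusted p = 0.44) for microglia, Nostrin (0.44, adjusted p = 0.155) for endothelium and Islr (-0.71, adjusted p = 0.122) for mural and meningeal cells. Bpgm (-0.16, adjusted p = 0.523), Ppp1r1b (-0.24, adjusted p = 0.653) and Synpo2 (0.56, adjusted p = 0.26) led blood, striatum and hippocampus or thalamus. In limma within the 9 arrays alone, genes that passed included Gad2 (1.105, adjusted p = 0.00827), Islr (-1.28, adjusted p = 0.00709) and Ehd3 (-1.21, adjusted p = 0.00848). Within the 11 these did not pass (-0.01, -0.24 and 0.08, adjusted p = 0.975, 0.712 and 0.812). In 10 lists the median, the mean and camera's direction did not share 1 sign, namely activity-regulated, glucocorticoid, heat shock, endoplasmic reticulum stress, oxidative stress, GABA-A, clock, interneuron, myelin and blood genes.

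**Figure D3:**
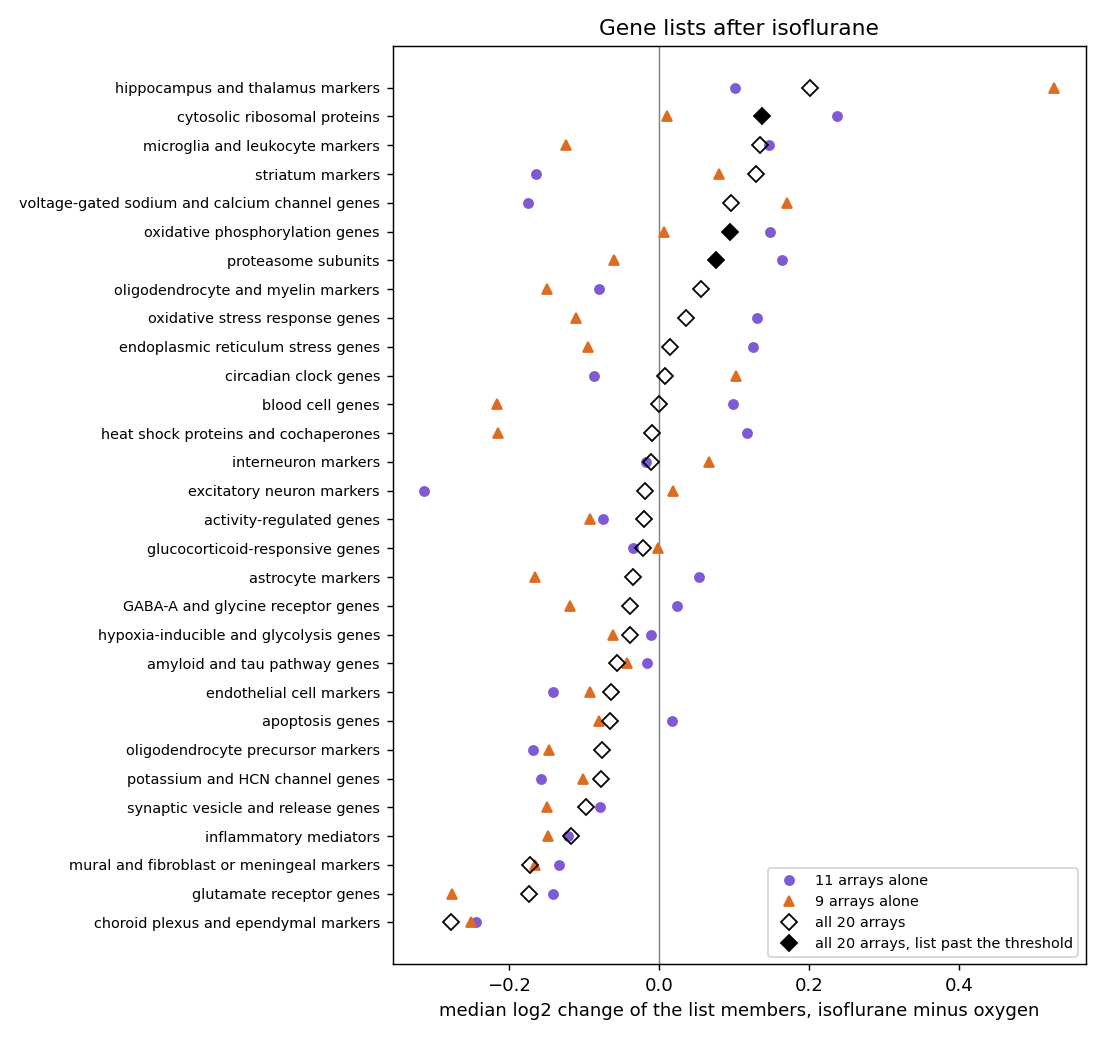
Each row is a gene list and the horizontal axis is the median log2 change of its members, isoflurane minus oxygen. Diamonds use all 20 arrays and are filled for the 3 lists past the threshold, circles use the 11 arrays and triangles the 9. The ribosomal list lay at 0.14 over all arrays, 0.24 over the 11 and 0.01 over the 9.

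Immediate early and stress hormone genes named beforehand did not pass. Fos changed by -0.21 ± 0.45 SE (adjusted p = 0.893), Arc by -0.34 ± 0.39 (adjusted p = 0.747) and Egr1 by -0.02 ± 0.46 (adjusted p = 0.987). The neurotrophin gene Bdnf changed by 0.07 ± 0.18 SE, the glucocorticoid-induced genes Fkbp5 and Sgk1 by 0.00 ± 0.20 and -0.11 ± 0.13, and the inducible chaperone gene Hspa1a by -0.34 ± 0.21, none below an adjusted p of 0.472. Hspa5, the chaperone BiP, changed by 0.24 ± 0.08 SE (adjusted p = 0.125). Cell type genes were Gfap of astrocytes at -0.39 (adjusted p = 0.253), Mbp of myelin at 0.21 (adjusted p = 0.544) and Cldn5 of endothelium at 0.06 (adjusted p = 0.891). Ttr, a gene of the choroid plexus, changed by -1.70 ± 0.89 SE (adjusted p = 0.366). Within the 9 arrays Gfap fell by 0.78 (adjusted p = 0.0132) and Ttr fell by 2.97 (adjusted p = 0.0179), and neither passed within the 11 (0.02 and -0.28, adjusted p = 0.906 and 0.911). For both genes isoflurane replicates 2, 4, 5 and 6 lay below the oxygen arrays of the 9 and isoflurane replicate 10 within their range. Neither passed with those 4 arrays left out and the block added (-0.04 and -0.62, adjusted p = 0.814 and 0.75). Npas4 was not among the genes with a tested probe set that names 1 gene.

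The third comparison followed the stated purpose of building networks. Among the 2000 brightest genes, 19.0% of gene pairs reached an absolute Pearson r of 0.8 over the 10 isoflurane arrays and 12.6% over the 10 oxygen arrays. The difference of 6.44 percentage points was within the range of other splits of the arrays (two-sided permutation p = 0.17 over 100 splits, other splits from -9.75 to 13.9). The genes with most edges after isoflurane were Btg1 with 911, Nop53, Slc20a1 and Eif3l with 909 each, and Gpbp1 with 908. After oxygen they were Cep170b with 703, Pfn2 with 702, and Psat1, Pnp and Rasgef1a with 699 each. None of these 10 genes passed the test between groups without the block, and 2 fell in the blocked fit, Cep170b (-0.44, adjusted p = 0.00909) and Pnp (-0.30, adjusted p = 0.0492). The 50 genes with most edges shared 4 members between the networks (one-sided permutation p = 0.11, median of other splits 16). The 50 most-connected genes of each network differed more between the 2 sets of arrays than the network genes overall. Their median absolute difference between the sets was 1.19 for isoflurane and 1.25 for oxygen in log2 terms, against 0.27 over all 2000 genes. With values centred within each group and set, density was 5.91% after isoflurane and 5.98% after oxygen (p = 1), and 7 of the 50 genes were shared (p = 0.32). Without replicate 9 of both groups, density differed by 12.2 percentage points (permutation p = 0.01, the smallest that 100 splits can give). With any other replicate left out the permutation p ran from 0.06 to 0.51. These fits were centred by group only and were not repeated with values centred within each set.

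The spread between rats did not differ detectably between groups. The median SD of a probe set was 0.36 after isoflurane and 0.35 after oxygen, and the median log2 ratio of SDs was 0.02 (permutation p = 0.78 over 100 splits), or -0.07 with values centred within each set (p = 0.7). The 3'/5' ratio of the control transcripts beta-actin and Gapdh, which rises when RNA is degraded or incompletely copied, averaged 0.91 ± 0.16 (SD, n = 10) after oxygen and 1.02 ± 0.38 after isoflurane in log2 terms. The difference of 0.11 did not pass (permutation test, two-sided p = 0.389), nor did it with the array set as a block (0.08, permutation p = 0.452), within the 11 arrays (-0.10, exact permutation p = 0.212) or within the 9 (0.29, exact permutation p = 0.159). On isoflurane replicates 2, 4, 5 and 6 the mean ratio lay between 1.28 and 1.59, against 0.63 to 1.23 on the other 16 arrays. Their beta-actin ratio lay between 2.30 and 2.86, against 1.09 to 1.98, and their Gapdh ratio, 0.24 to 0.33, inside the range of the others.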

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

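Tests chosen only after the result was seen were those of RNA quality, array scaling and isoflurane for the 2 sets of arrays, that of 1 factor for all genes, those of RNA quality and RNA degradation for the 4 isoflurane arrays, the second chosen once the first had come out, that of the change on other rats, and all fits that use the 2 sets or leave those 4 arrays out.

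Of 174 groups of 10 values examined, 13 held an array far from the others. Chance alone gives about 1 in 20, or 8.7, for independent values from 1 normal distribution. Here each group held arrays of both sets and the genes are not independent, so 13 cannot be weighed against 8.7. Isoflurane replicate 9 accounted for 8 of the 13. It was the highest isoflurane array for Prr12 (10.5, nearest 9.04), Ptpn23 (9.2, nearest 8.09), Mknk2 (9.64, nearest 8.63), Kcnc4 (10.1, nearest 9.3), Cdc42bpb (10.1, nearest 9.37) and Usp2 (10.8, nearest 10.3), and the lowest for Gad2 (7.66, nearest 8.61) and Mbp (13.7, nearest 14.2). For all 8 genes this array lay on the oxygen side, beyond the oxygen mean. Those means were, in the same order, 10.0, 8.81, 9.33, 9.92, 9.99, 10.57, 8.39 and 14.19. For Nr1d1, Vegfb and Fa2h it lay below the oxygen mean, as the other isoflurane arrays did. Why this array differed was not tested. Isoflurane replicate 10 was highest for Fa2h (10.3, nearest 9.92) and for the striatal signalling gene Ppp1r1b (12.7, nearest 11.8). Isoflurane replicate 7 was highest for Enpp6 (7.67, nearest 7.13), oxygen replicate 3 for Psmb1 (12.5, nearest 12.2), and oxygen replicate 8 was lowest for Cldn5 (10, nearest 10.4).

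The first pattern is the split of the 20 arrays into 11 and 9 by 5 cerebellar genes, which differed by a median of 6.13 (SD 0.633) with arrays centred on their medians, a value that excludes no array scaling, since these genes define the sets and each lay below the filter on at least 1 of the 9 arrays. A split set by the mean 3'/5' ratio alone was argued against, since 2 of the 9 arrays (oxygen replicate 1 and isoflurane replicate 10) had a ratio inside the range of the 11. The rest of the 9 had ratios of 0.997 to 1.59, above all of the 11 (0.626 to 0.987). A difference in RNA quality between the sets is therefore not excluded. Isoflurane was argued against, with both groups in both sets (Fisher's exact p = 1). So was 1 scaling factor for all genes, since the medians of the cerebellum markers described next and of the forebrain markers, 11 of each above the filter on every array, lay 3.67 apart in log2 terms (larger SD 0.922). A candidate explanation is cerebellar tissue on the 11 arrays, although the labels give cortex for all 20 samples. The 13 measured cerebellum markers not looked at before had a median log2 difference of 1.80 between the sets, all 13 higher on the 11 arrays. The medians of 10000 random lists matched on signal ran from -0.71 to 0.67. Of these 13, 11 also lay above the filter on every one of the 9 arrays and 5 were in a fixed list, and the most abundant, Pvalb and Itpr1, ran from 13.23 to 14.10 and from 13.20 to 13.93 on the 11 arrays. The 17 measured forebrain markers, 13 of them in a fixed list, had a median difference of -1.93 with 16 lower on the 11 arrays, and whether dissection, labelling or sample handling placed them there stays open.

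The second pattern is that isoflurane replicates 2, 4, 5 and 6 correlated at 0.976 to 0.982 with one another but at 0.855 to 0.922 with the 4 oxygen arrays of the 9, while isoflurane replicate 10 correlated at 0.927 to 0.973 with those oxygen arrays and at 0.906 to 0.922 with the 4. A response shared by both sets stays open: the change within the 11 arrays was a median of 0.0866 times that within the 9 over the 3469 probe sets called there, which that choice makes too low, and 0.109 times that of rats not used to choose the probe sets (95% interval over resampled rats -0.149 to 0.408, not below the bound of 0.25), while the 74, chosen over all arrays, had medians of 0.44 and 0.77 in their own direction within the 11 and the 9. RNA quality may contribute and stays open: 0 of the 4 arrays had a mean 3'/5' ratio of beta-actin and Gapdh inside the range of the other 16 (1.28 to 1.59 against 0.63 to 1.23), while degradation that raises the ratio of all transcripts was argued against, since only 1 of 3 control transcripts (beta-actin) was raised on all 4 and hexokinase was lower, at -0.75 to -0.27 against 0.84 to 2.47. The difference between groups varied between the sets for 1897 probe sets in limma. Of 100 splits within the sets 1, the real one, gave as many (highest other 92), which argues against a random split for that count. The 4 isoflurane arrays all lie among the 9, so the count cannot tell an unequal response from another difference of those 4 arrays. The mean log2 signal of the cerebellar genes that define the sets also differed, at 4.43 to 5.29 on those 4 arrays. It was 6.70 to 8.01 on the 4 oxygen arrays of the 9 and 9.53 on isoflurane replicate 10. The values of the 4 isoflurane arrays lay below the filter. Some forebrain markers above it also parted these 4 from the 4 oxygen arrays, in both directions. Wfs1 (7.90 to 8.21 against 9.31 to 9.71) and Sst (10.91 to 11.38 against 11.76 to 11.89) were lower. Neurod2 was higher (9.52 to 9.98 against 8.40 to 9.20), and others, such as Lmo4 and Dlx1, overlapped. On isoflurane replicate 10 Wfs1 was 8.92, Sst 11.74 and Neurod2 8.83. A difference in the tissue taken therefore stays open. An isoflurane response limited to the tissue of the 9 arrays and a difference in labelling or processing of those 4 isoflurane arrays also stay open. None of these was tested, and no batch is given in the labels used here.

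The third pattern is the count of 74 probe sets. Of 100 splits 2, the real one included, gave as many, fewer than the bound set beforehand, which argues against a random split in general. The highest other, 369, held all 4 of the isoflurane arrays that stand apart in 1 group, as the real split does. A chance placement of those 4 arrays in 1 group is therefore not excluded. With the array set as a block 1 of 100 splits gave as many as 1372 (highest other 781). Within the 9 arrays 2 of 100 gave as many as 3469. The highest other there, 6109, set the 4 isoflurane arrays that stand apart against the rest of the 9. The 3469 calls can therefore not be credited to isoflurane alone. Within the 11 arrays, where limma called 0 (2376 at an unadjusted p under 0.05), all 100 had to reach that (highest other 2813), which says nothing on chance. With the mean 3'/5' ratio of beta-actin and Gapdh as a covariate 100% of the 74 kept their call, which argues against a cause that follows this mean ratio alone. The covariate left out hexokinase, whose ratio set the 4 isoflurane arrays apart and was not tested between groups. RNA quality, of those 4 arrays above all, therefore stays open here too. Variation already present among oxygen arrays may contribute and cannot be told apart here: across probe sets, which are not independent replicates, the blocked log2 change correlated with the first component of the oxygen arrays at an absolute Pearson r of 0.442, between the bounds set beforehand. Without the 4 isoflurane arrays limma called 0 with or without the block (3016 and 2488 at an unadjusted p under 0.05), the median change of the 74 in their own direction being 0.47 (SD 0.19 over probe sets, median SE 0.13) against 0.60 (SD 0.29, median SE 0.12) with them, and removing single other arrays lowered the count nearly as far (3 without oxygen replicate 4 or isoflurane replicate 7), so how much the loss owes to fewer arrays stays open.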

How the results depend on the processing

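The array sets and the removal of 4 isoflurane arrays were chosen after seeing the data. Where a result changed, the cause was not tested. The count of 74 probe sets became 41 with quantile normalization, 15 with arrays centred on medians, 16 without the eBayes trend, 337 with array weights, 289 with the 3'/5' covariate, 16 without a filter and 125 at the 60th percentile. It was 1372 with the array set as a block, 0 and 3469 within the 11 and the 9 arrays, and 0 without the 4 isoflurane arrays, with the block too (3016 at an unadjusted p under 0.05). Single arrays moved it to 4, 11, 16, 3, 7, 114, 9, 5 and 9 without oxygen replicates 1, 2, 3, 4, 5, 6, 7, 8 and 10, and to 4, 2, 7, 3, 3, 6, 3, 5 and 838 without isoflurane replicates 1 to 9. Replicate numbers mark different rats. Correlations of deviations between arrays of the same number ran from -0.659 to 0.616, and no array was best with its own number. These correlations were positive where both arrays lay in the same set (0.104 to 0.616) and negative where they did not (-0.659 to -0.366). They follow the sets, so they cannot tell whether the numbers paired rats in another way. The replicate block gave 0 calls in limma (2348 at an unadjusted p under 0.05). The 3 lists became 6 within the 11 arrays, 0 within the 9, 10 without the 4 arrays (4 up, 6 down) and 7 with the block added, 0 with an estimated correlation in all of these fits (3 at an unadjusted p under 0.05 within the 11) and over all arrays, 0 by fry (6 at an unadjusted p under 0.05), and 2 to 4 without 1 array. The log2 changes of Ttbk2 and Grin1 became -0.0176 and 0.0559 as means of all probe sets. Over 82 named genes and their alternatives, 2255 values kept their side of the threshold, 440 lost it and 91 gained it, and 92 of the 2255 changed sign without passing. The network difference ran from 3.4 to 12.2 points without 1 replicate. Shared hubs were 5 at an absolute r of 0.9 (permutation p = 0.03), 0 with Spearman correlation, 8 with 1000 genes, 2 with 4000, 10 with quantile normalization, 7 when centred by set, and 2 to 8 without 1 replicate. The ratio of SDs stayed short of the threshold throughout. The 3'/5' difference turned to -0.0882 with Gapdh alone (permutation p = 0.0452). Signal over background was not given, so dim genes are the least certain.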

Other observations

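The values here come from fits chosen after seeing the data, and the genes were chosen after their values were seen. With the array set as a block, 7 of 40 synaptic vesicle and release genes fell. Among them, Syn1, a phosphoprotein of synaptic vesicles, changed by -0.70 ± 0.13 SE (limma adjusted p = 0.00873), Stx1a, a plasma membrane protein of vesicle fusion, by -0.89 ± 0.20 (adjusted p = 0.0157) and Vamp2, its vesicle partner, by -0.55 ± 0.13 (adjusted p = 0.021). Within the 11 arrays these were -0.62, -0.82 and -0.56 and within the 9 they were -0.79, -0.98 and -0.54. Kainate receptor genes went both ways, Grik5 at -0.55 ± 0.13 SE (adjusted p = 0.0187; -0.63 within the 11 arrays and -0.46 within the 9) and Grik2 at 0.46 ± 0.11 (adjusted p = 0.021; 0.23 and 0.74). The myelin transcription factor genes Sox10 and Myrf changed by -0.70 ± 0.16 and -0.59 ± 0.15 (adjusted p = 0.0179 and 0.0284), with -0.52 each within the 11 arrays and -0.91 and -0.68 within the 9. None of these genes passed without the block or within the 11 arrays alone.

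Ttr, carried by choroid plexus, was the most variable of the genes named in advance. Its log2 signal ran from 7.70 to 13.7 over the oxygen arrays and from 7.63 to 13.7 over the isoflurane arrays. On isoflurane replicate 10 the cerebellar genes Pcp2, Cbln1, Gabra6, En2 and Fat2 exceeded their mean on the other 8 of the 9 arrays by a median of 8.24% of the distance from that mean to the mean of the 11 arrays, on the linear scale, with 6.53% for En2 the lowest of the 5.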
